A study of Mus musculus with 12 samples.

How the data were processed

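Total RNA from vascular smooth muscle cells of male mice was amplified, labelled with cyanine-3 and hybridised to custom Agilent arrays, 1 sample per array, per the labels' protocols. A separate label field names biotin; the single green channel was used as deposited. The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12, per the file headers. The submitters' processing notes name version 9.1. The deposited value table of the series holds log2 intensity; set against the scanner values of the same probes, it differed from them by a constant to within 0.01 for every probe on 9 arrays and for all but 1 probe on each of the other 3, and the 75th percentile of each array lay near 0. How the authors made that table is not given in the sources used here, and it served as an alternative. The array design names build mm9, per the file headers, and no coordinates were used.

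Each array held 175906 spots outside the controls, for 97836 probes, 78070 of them on 2 spots and 19766 on 1. Spots with outlier marks were left out unless all spots of the probe had one, the spots of a probe were averaged as log2 of the processed signal (gProcessedSignal, already background-corrected), and the 75th percentile of each array was subtracted. Probes well above background on all 3 arrays of at least 1 group were kept (70909). Where a gene symbol had several probes, the probe with the highest mean was used, which left 70784 features. Groups were taken from the labels.

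Gene names came from a RefSeq table of assembly GRCm38.p6, used for names and neighbouring genes only. Of 13019 probes with a RefSeq noncoding accession, 4658 matched 4290 symbols. Of these probes, 230 had a symbol that is not a predicted or clone name. Such a probe reports a noncoding record of the gene, also where the gene encodes a protein. Of 15675 RIKEN clone probes, 1256 matched a symbol or synonym and were described only as clones linked to a locus. The 39027 probes with Agilent catalogue names have no gene name in the sources used here and entered only counts. Of 906 genes on 34 lists prepared for smooth muscle, hypoxia and other cell types, 2 were matched by accession (Mx2 and Tsix) and 21 by clone. The largest list had 4 members by either route, so list tests were void, no result of a list as a group is given, and markers of other cell types were not assessed.

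The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 12 arrays with 1 mean per group, Benjamini-Hochberg adjusted p below 0.05), with 5 contrasts: CoCl2 in floxed cells, CoCl2 in deleted cells, deletion under PBS, deletion under CoCl2, and the difference of the CoCl2 effects. The fit had 8 residual and 3.51 prior degrees of freedom. Probe classes, and noncoding genes beside members of the prepared lists, were tested with camera, with a preset correlation of 0.01 and again with an estimated one. A probe not well above background on any array of a group has only a bound there: the mean of the brighter group was set against the mean of, per array, the higher of the probe's own signal and the lowest signal of probes well above background. Simulated data had 200 of 70784 features changed in the contrast of CoCl2 in floxed cells. There limma recovered 19.5% of changes of 1 on the log2 scale and 82.0% of changes of 2, with 2 and 8 false calls. The simulated noise was independent, without slides or pairs, and fewer features changed than any real contrast called. These shares and false calls therefore do not carry over to the real contrasts.

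The rule for named genes, fixed before the data were examined, took Hif1a, the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap (for the difference of effects, without that condition) and an established symbol, and members of the prepared lists. Only accession matches counted as established symbols. Pgk1 is among the genes always named. The Gapdh, rat, human, E1A and ERCC control probes were chosen after their values were seen.

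The arrays lay on 3 slides. Slide 1 held 3 floxed PBS arrays and 1 floxed CoCl2 array, slide 2 held 2 floxed CoCl2 and 2 deleted PBS arrays, and slide 3 held 1 deleted PBS and 3 deleted CoCl2 arrays. Of these, 1 deleted CoCl2 array was scanned 4 days after the others. Within slides the arrays lay in sample order. On slides 1 and 3 the PBS arrays held the positions before the CoCl2 arrays. A comparison of treatments within a slide therefore cannot be told apart from position. Array numbers in the titles were checked for pairing. Same-numbered floxed PBS and CoCl2 arrays deviated together from their group means (correlations 0.397 to 0.452), and all 6 floxed arrays matched their own number best. The numbers may pair these arrays, but the 6 matches are not independent, because deviations within a group cancel. Deleted PBS and CoCl2 arrays did not all deviate together by number (correlations -0.144 to 0.285).

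Alternatives planned before the data were examined were quantile normalization, normexp background correction with offset 50, scaling to probes above background on all arrays, other filters, slide as a fixed or random block, the replicate number as a block, fits of 6 arrays, eBayes with trend and robust, the deposited value table, a 2-fold threshold and leaving out each array. The deposited files give no mean signal, so normexp used the median signal and median background. Scaling to 4 or to all 10 E1A control probes, a replicate block within genotype, and a fit of the 9 arrays without deleted CoCl2 were added after seeing the data. The 4 E1A probes were picked because their raw level stayed similar between groups, which makes that scaling circular as a check. Their mean raw log2 level was uneven within the deleted CoCl2 group, at 10.58, 11.69 and 10.69 on arrays 1, 2 and 3. The SD there was 0.61, against 0.11 to 0.32 in the other groups, and array 2 was the one scanned later. The mean of all 10 E1A probes is no constant reference either. All those not picked had a lower mean raw log2 signal on deleted CoCl2 than on floxed PBS arrays. Examples are 9.25 against 11.93 for probe a22 and 4.40 against 8.90 for probe a107, while the mean of the 4 picked probes was 10.99 against 10.82. Whether E1A RNA was added to the samples is not given in the sources used here. In 2 tests of explanations, of cross-hybridisation and of slide in floxed cells, the measure was replaced after a first result was seen. The first used only the rat Pgk1 3′ probe, the one that moved farthest, and was replaced by all 8 cross-species probes. That probe was not well above background on the deleted CoCl2 arrays, and it later entered with the lowest signal of probes well above background there, as a bound. The second used the sign of the changes in deleted cells, which a trend across slides could also give, and was replaced by arrays within slide 1.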

Results

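RNA from vascular smooth muscle cells (VSMCs) of male mice was measured on 12 single-colour Agilent arrays. The cells carried either floxed, intact Hif1a alleles or a smooth-muscle-specific disruption of Hif1a, which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1. Each genotype was exposed for 24 h to 150 µM cobalt chloride (CoCl2), a chemical that blocks the oxygen-dependent degradation of HIF-1alpha, or to an equal volume of phosphate-buffered saline (PBS). This gave 4 groups of 3 arrays. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

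The share of probes well above background was 72.2% ± 2.33 (SD, n = 3) in floxed cells with PBS, 75.7% ± 7.56 in floxed cells with CoCl2 and 73.2% ± 0.909 in deleted cells with PBS. It was 54.7% ± 3.43 (SD, n = 3) in deleted cells with CoCl2, and each of these 3 arrays (51.9% to 58.5%) lay below all others. The 75th percentile of log2 signal, to which each array was scaled, was 8.28 ± 0.10 in that group against 9.18 ± 0.08 in deleted cells with PBS. Correlations of log2 signal between arrays of a group ran from 0.969 to 0.994 across probes, which are not independent replicates. No probe with the name Hif1a was among those named here, so the disruption itself was not checked on these arrays.

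**Figure D1:**
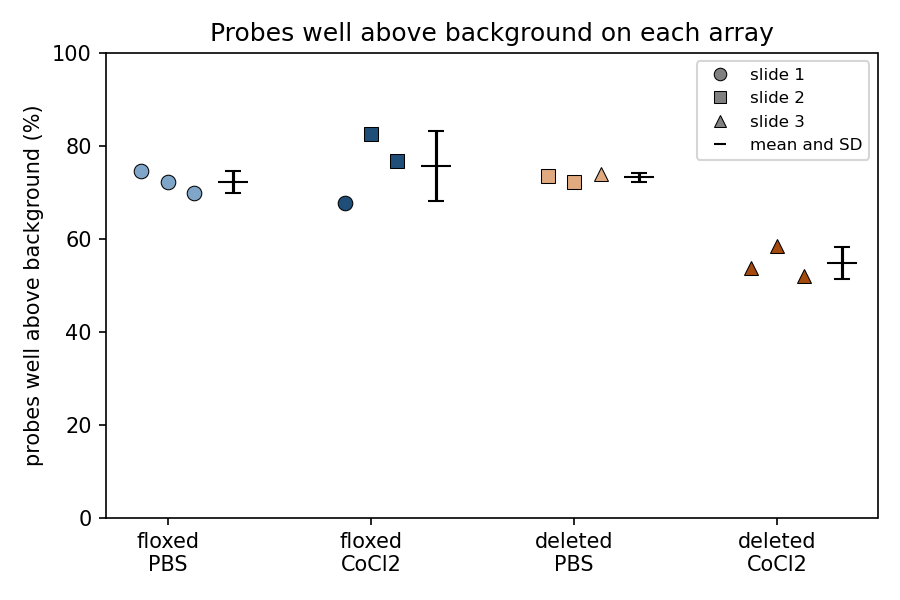
Share of probes well above background (%, vertical axis) on each array, by group; symbols give the slide and bars the mean and SD of 3 arrays. The 3 arrays of deleted cells with CoCl2 (51.9% to 58.5%) lie below the other 9, and all 3 are on slide 3; the other array of slide 3, of deleted cells with PBS, stands at 74.0%.

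The first question was which transcripts responded to CoCl2 in cells with intact Hif1a. Mir22hg, the host transcript of a microRNA, rose 1.69-fold (log2 change 0.76, SE 0.17, n = 3 per group, limma adjusted p = 0.0253), and the long noncoding RNA Wincr1 rose 1.90-fold (0.93, SE 0.18, adjusted p = 0.0151). The noncoding transcript records of Bcor, a transcriptional corepressor gene, and of Alg13, a gene of protein glycosylation, fell by 1.41 (SE 0.22, adjusted p = 0.00489) and by 0.77 (SE 0.16, adjusted p = 0.0173) on the log2 scale. Zeb2os, which lies beside the transcription factor gene Zeb2, fell by 1.12 (SE 0.20, adjusted p = 0.00898). Rnf227 fell by 1.32 and Sox5os4 by 1.41, with adjusted p of 0.0248 and 0.045. These 7 were the only genes past the threshold among the 161 tested that carry an established symbol.

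In floxed cells, probes for RIKEN cDNA clones linked to 19 genes of the prepared lists were tested on 20 clones. Such a probe can report another transcript of the locus than the coding one. The clone at Sod1, the locus of cytosolic superoxide dismutase, rose 2.95-fold (log2 change 1.56, SE 0.27, adjusted p = 0.00857), and the clone at Col11a1, a fibrillar collagen gene, fell by 2.04 (SE 0.51, adjusted p = 0.0425). These were 2 of 20 clones past the threshold over all features, and 2 of 20 when adjusted over the list alone. The clones at Atg12 (0.64, SE 0.21) and Fbln2 (-1.23, SE 0.41) did not pass. Of all 70784 features tested, 3542 changed, 1639 upward and 1903 downward, and 2031 of them by at least 2-fold. With slide as a block, which compares the 1 CoCl2 array on slide 1 with the 3 PBS arrays there, 547 features passed and none of these 9 named genes and clones did, with log2 changes from -1.67 to 1.21 in the unchanged directions. The replicate number as a block ended the call of the Col11a1 clone (limma adjusted p = 0.0704) and left the other 8. That block uses the same offset per number for both genotypes, so it is no paired test of the floxed arrays alone. The named results were not read under the block within genotype, which would pair them. Leaving out 1 array lowered the count to 2145, 1395 or 1790 (floxed PBS array 1, 2 or 3) and to 2100 or 1093 (floxed CoCl2 array 2 or 3). The named results were as fragile: 7 of the 9 lost the call without floxed CoCl2 array 3, 6 without floxed PBS array 2 and 4 without floxed PBS array 1. Scaling to 4 E1A control probes ended 6 of the 9 calls and scaling to all 10 ended 5. The Sox5os4 call was lost in 14 alternatives and that of the Col11a1 clone in 15. The 3′ minus 5′ signal of Pgk1, a sign of RNA quality, was 2.72 ± 0.03 (SD, n = 3) with CoCl2 against 2.82 ± 0.02 with PBS, and that of Gapdh -1.91 ± 0.13 against -2.32 ± 0.02.

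The second question was how cells with disrupted Hif1a responded to the same exposure. Gssos2, a transcript antisense to the glutathione synthetase gene Gss by its name, rose 7.20-fold (log2 change 2.85, SE 0.41, n = 3 per group, limma adjusted p = 0.000298). Wincr1 rose 2.28-fold (1.19, SE 0.18, adjusted p = 0.000434), Mir22hg 2.20-fold (1.14, SE 0.17, adjusted p = 0.000347) and Norad, a cytoplasmic long noncoding RNA that binds Pumilio proteins, 2.01-fold (1.01, SE 0.17, adjusted p = 0.000698). Scarna13, a small Cajal body RNA, rose 2.20-fold. These rises apart from Gssos2 depended on the scaling: under a scaling to 4 E1A control probes Wincr1, Mir22hg and Scarna13 stood at 0.12, 0.07 and 0.07 (adjusted p from 0.733 to 0.866) and Norad turned to -0.06, while Gssos2 kept 1.78. The mean raw level of these 4 probes was itself uneven across the deleted CoCl2 arrays (10.58, 11.69 and 10.69). The noncoding record of Scnn1b, a subunit gene of the epithelial sodium channel, fell by 2.02 on the log2 scale (SE 0.28, adjusted p = 0.000262), and that of Mphosph9 by 2.01 (SE 0.38, adjusted p = 0.00126).

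Among antisense transcripts in deleted cells, Cdrt4os1 fell by 2.87 (SE 0.47), Kcnd3os by 2.62 (SE 0.32), Plxna4os1 by 2.53 (SE 0.63) and Pitpnm2os1 by 1.82 (SE 0.46). Pcsk2os2 was at least 1.18-fold lower and the pseudogene Ppp1r2-ps7 at least 2.72-fold lower, because neither was well above background on any deleted CoCl2 array. Mx2, the only tested member of the interferon list with an accession match, was at least 2.44-fold lower (adjusted p = 0.000575). In all, 87 of the 161 genes with an established symbol changed, 27 upward and 60 downward. Of the 20 clones linked to listed genes, 7 passed over all features and 7 adjusted over the list alone. The clones at Sod1 and Atg12, an autophagy gene, rose 5.05-fold (2.34, SE 0.27) and 2.55-fold (1.35, SE 0.21); under the scaling to 4 E1A control probes Sod1 kept 1.26 and Atg12 lost the call at 0.28 (adjusted p = 0.424). The clone at Kif2c, a mitotic kinesin gene, fell by 0.85 (SE 0.20), and the clone at Col11a1 fell by 1.88 (SE 0.51). Normexp and quantile normalization shrank the value of the Kif2c clone to -0.415 and ended its call (limma adjusted p = 0.0566).

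Over all features, 37380 changed with CoCl2 in deleted cells, 14115 upward and 23265 downward (37.8% upward), and 19466 changed by at least 2-fold. Of 6900 RefSeq model transcripts (XR records), 52.5% fell and 9.30% rose, with a median log2 change of -0.72, against -0.13 over all features. Their shift against the other features passed camera with a preset correlation (adjusted p = 3.64e-06) and not with an estimated one (adjusted p = 0.384). Deletion under PBS gave the same direction, with a median of -0.27 (camera adjusted p = 3.65e-07 preset and 0.318 estimated). Changes also went with signal on the 9 arrays other than deleted CoCl2. The median was -0.57 among the 17696 features with the lowest signal and 0.24 among the 17696 with the highest. Whether signal accounts for the class was not tested. Among the 47149 features well above background on all 12 arrays, 13264 rose and 8908 fell. By construction this selection removes features that fell to background, with 14357 falls and 851 rises outside it, so its upward majority is no measure of direction. The upward share depended on the processing: it was 0.765% when scaled to 4 E1A control probes, 25.6% when scaled to probes above background on all arrays, 44.2% after quantile normalization, 47.3% after normexp and quantile normalization and 49.4% with no filter (23517 upward and 24062 downward). With slide as a block, which compares the 3 CoCl2 arrays on slide 3 with the 1 PBS array there, 16377 features passed, and 12 of 28 named genes and clones lost the call. The log2 changes of the 28 then ran from -2.51 to 2.99, against -2.87 to 2.85 without the block. Pgk1 3′ minus 5′ signal, a sign of RNA quality, was 2.67 ± 0.19 (SD, n = 3) with CoCl2 against 3.07 ± 0.05 with PBS. That of Gapdh moved the other way, at -2.12 ± 0.14 against -2.25 ± 0.09.

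**Figure D2:**
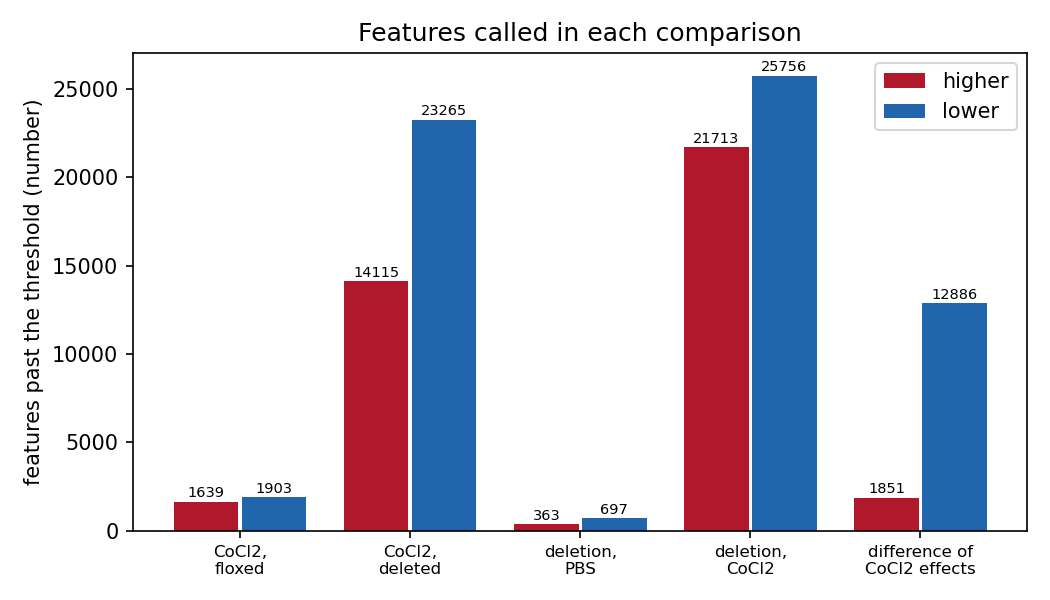
Number of features past the limma threshold (vertical axis) in each of the 5 comparisons, higher (red) and lower (blue), of 70784 tested. In deleted cells with CoCl2, 14115 were higher and 23265 lower; the last pair counts features whose CoCl2 effect differed between genotypes.

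The responses of the 2 genotypes share no arrays, but both use the estimate of each feature's spread from the 1 fit. A feature with a small spread is called more readily in both, so the counts for independent lists may be too low as a baseline. Of the 1639 features that rose with CoCl2 in floxed cells, 1523 also rose in deleted cells (92.9%), where independent lists would share 327. Of the 1903 that fell, 1277 also fell (67.1%), where independent lists would share 625. Features called in floxed cells had the same sign in deleted cells in 97.7% of the rises and 96.7% of the falls. Wincr1 and Mir22hg were among the shared rises. In both genotypes most CoCl2 arrays lay on the slide after that of most PBS arrays, and with slide as a block 356 features were shared in place of 2800. Scaled to 4 E1A control probes 937 were shared, 184 of them rises, and scaled to all 10 it was 1253 with 460 rises. Leaving out 1 array lowered the 2800 to 1719, 1228 or 1448 (floxed PBS array 1, 2 or 3) and to 1784 or 979 (floxed CoCl2 array 2 or 3).

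Pgk1, a glycolytic enzyme gene and textbook target of HIF-1, was measured by control probes of 10 spots each. The mouse 3′ probe rose with CoCl2 by 1.72 on the log2 scale in floxed cells (SE 0.16, n = 3 per group, limma adjusted p = 0.000344) and by 1.70 in deleted cells (SE 0.16, adjusted p = 3.54e-05). The difference between genotypes was -0.02 (95% interval -0.51 to 0.46, adjusted p = 0.951). The 5′ probe rose by 1.82 (SE 0.18) in floxed and by 2.10 (SE 0.18) in deleted cells. Under a scaling to 4 E1A control probes the rise of the 3′ probe was 0.63 in deleted cells (adjusted p = 0.0417) against 1.57 in floxed cells, with a difference of -0.94 (adjusted p = 0.0544). The mouse Gapdh 3′ probe, of another glycolytic gene, rose by 0.85 in floxed cells (SE 0.13, limma adjusted p = 0.0048) and by 0.98 in deleted cells (SE 0.13). Under the 4-probe scaling its value in deleted cells turned to -0.09. The mean of the mouse Gapdh 5′ probe went from 6.34 to 6.78 with CoCl2 in floxed cells and from 6.52 to 7.37 in deleted cells. On slide 1 the CoCl2 array stood at 5.36 for the Pgk1 3′ probe against 3.56 to 3.83 on the 3 PBS arrays, and on slide 3 the 3 CoCl2 arrays stood at 5.79 to 6.20 against 4.36 on the PBS array. Within arrays, Pgk1 3′ signal minus Gapdh 3′ signal rose by 0.87 in floxed cells (95% interval 0.58 to 1.16) and by 0.72 in deleted cells (0.42 to 1.01). Between the 5′ probes the rises were 1.38 (0.99 to 1.76) and 1.25 (0.86 to 1.63).

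**Figure D3:**
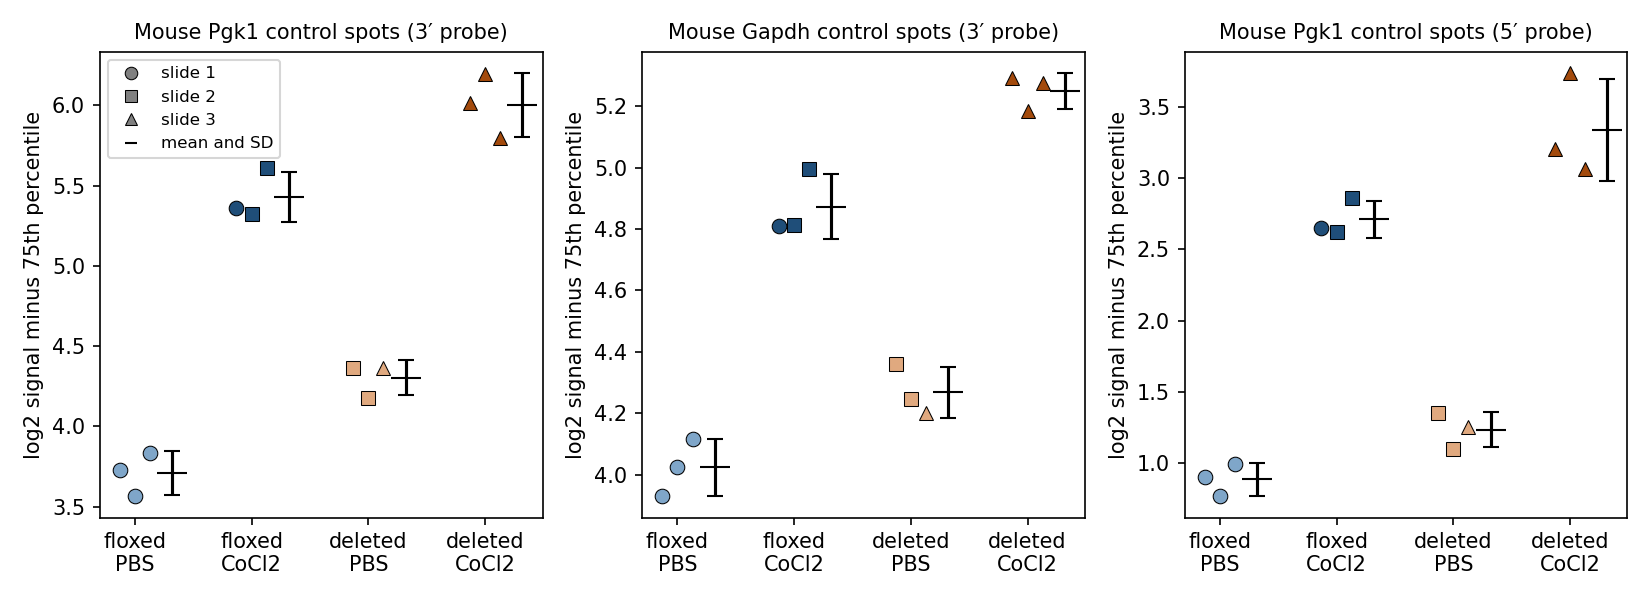
Normalized log2 signal (vertical axes, different ranges) of the mouse Pgk1 3′, Gapdh 3′ and Pgk1 5′ control probes on each array; symbols give the slide and bars the mean and SD of 3 arrays. Pgk1 3′ rose by 1.72 in floxed and 1.70 in deleted cells with CoCl2; under a scaling to 4 E1A control probes the Gapdh 3′ value in deleted cells turned to -0.09.

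The third question was what the disruption of Hif1a changed without CoCl2. All 6 genes with an established symbol past the threshold were lower in deleted cells. Dlx4os fell by 1.43 (SE 0.31), Scnn1b by 1.31 (SE 0.28), Kif4-ps by 1.04 (SE 0.21) and Serpina3h by 1.42 (SE 0.29) on the log2 scale, and Pmis2 and Cyp2d13 by 1.02 and 0.96, with limma adjusted p from 0.043 to 0.0477 (n = 3 per group). No clone linked to a listed gene passed with limma over all features (5 of 20 at unadjusted p below 0.05), and 2 passed adjusted over the list alone, those at Dusp4 (log2 change 1.05, SE 0.28), a MAP kinase phosphatase gene, and at Cald1 (0.66, SE 0.19), the caldesmon gene. Mx2 was not past the threshold (-0.34, SE 0.24). Over all features 363 were higher and 697 lower, 1060 in all, with 34.2% higher; the higher share was 12.4% when scaled to probes above background on all arrays and 80.3% of 66 when scaled to 10 E1A control probes. This count rested on single arrays: it was 5, 2 or 383 without floxed PBS array 1, 2 or 3, it was 1, 52 or 14 without deleted PBS array 1, 2 or 3, and it was 4690, 33 or 21 without floxed CoCl2 array 1, 2 or 3. No slide held both floxed PBS and deleted PBS arrays, so this comparison cannot be made within a slide. A fixed block for slide reaches it only through the floxed CoCl2 arrays of slides 1 and 2. With that block 1737 features passed but 5 of the 6 genes did not, and with slide as a random block 12 features and none of the 6 genes passed. The values of the 6 genes ran from -2.37 to -0.97 and from -1.59 to -0.99, against -1.43 to -0.96 without a block. The replicate number as a block ended the calls of Serpina3h and Pmis2. Normexp and quantile normalization shrank Dlx4os to -0.38 and Serpina3h to -0.45 and ended both calls (adjusted p = 0.0948 and 0.0668), and quantile normalization ended that of Dlx4os (adjusted p = 0.0588). All 6 genes lost the call when scaled to all 10 E1A control probes, and without any 1 of floxed PBS arrays 1 and 2, floxed CoCl2 arrays 2 and 3, and deleted PBS arrays 1, 2 and 3. Of 2 signs of RNA quality, 1 moved with the deletion: Pgk1 3′ minus 5′ signal was 3.07 ± 0.05 (SD, n = 3) in deleted against 2.82 ± 0.02 in floxed cells, with all 3 deleted arrays above all 3 floxed ones. That of Gapdh was -2.25 ± 0.09 against -2.32 ± 0.02, with arrays that overlapped.

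Under CoCl2, deleted and floxed cells differed more widely. The noncoding records of Hnrnpa1 and Rbmx, genes of RNA-binding proteins, were 2.49-fold (log2 change 1.32, SE 0.21, limma adjusted p = 0.000207) and 2.25-fold (1.17, SE 0.30, adjusted p = 0.00455) higher in deleted cells (n = 3 per group). The small nucleolar RNA host gene Snhg16 was 2.30-fold higher (1.20, SE 0.21), Alg13 2.18-fold (1.13, SE 0.16), Wincr1 2.10-fold (1.07, SE 0.18) and the pseudogene Pisd-ps3 2.55-fold (1.35, SE 0.18). Under the scaling to 4 E1A control probes the values of Rbmx, Alg13, Wincr1 and Snhg16 turned to -0.03, -0.08, -0.14 and -0.00, and those of Hnrnpa1 and Pisd-ps3 shrank to 0.12 and 0.15 and lost the call (adjusted p = 0.757 and 0.697). Scnn1b was lower by -3.06 on the log2 scale (SE 0.28, adjusted p = 9.52e-06), Kcnd3os by -3.30 (SE 0.32), Cdrt4os1 by -3.28 (SE 0.47) and Mphosph9 by -2.90 (SE 0.38). Transcripts not well above background on any deleted CoCl2 array were lower by a bound, at least 2.09-fold for Pcsk2os2, at least 1.84-fold for Sox1ot, at least 2.14-fold for Rab11fip4os1 and at least 3.19-fold for Mx2. Of the 161 genes with an established symbol, 44 were higher and 63 lower.

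Of the 20 clones linked to listed genes, 11 differed under CoCl2 over all features and 11 adjusted over the list alone, 8 higher and 3 lower in deleted cells. The clones at Dusp4 (1.29, SE 0.28), Nrp1 (1.31, SE 0.39), a semaphorin and VEGF co-receptor gene, Atg12 (0.93, SE 0.21) and the laminin gene Lamb1 (0.91, SE 0.25) were higher. The clones at Kif2c (-1.21, SE 0.20) and Ep300 (-0.72, SE 0.16), the gene of a HIF coactivator, were lower. Across the alternatives the value of the Ep300 clone ran from -1.92 to -0.28, and its call was lost in 2. Of the 32 named genes and clones of this comparison, 2 lost the call when scaled to all 10 E1A control probes. Under the scaling to 4 E1A control probes, the clones at Atg12 and Lamb1 turned to -0.27 and -0.29, and those at Dusp4 and Nrp1 shrank to 0.09 and 0.10 and lost the call (adjusted p = 0.842 and 0.836). Over all features 21713 were higher and 25756 lower, 47469 in all, and 25438 differed by at least 2-fold. The higher share was 45.7%, against 28.4% when scaled to probes above background on all arrays, 0.216% when scaled to 4 E1A control probes and 61.4% when scaled to all 10. A block for slide reaches this comparison only through the chain of slides. Under it 18672 features passed and 18 of 32 named genes and clones lost the call. The log2 changes of the 32 then ran from -2.84 to 1.45, against -3.30 to 1.77 without the block.

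The last question was whether the CoCl2 effect itself differed between genotypes. All 29 established genes past the threshold had a lower value in deleted than in floxed cells. The difference was -2.86 for Cdrt4os1 (SE 0.66, limma adjusted p = 0.0133, n = 3 per group), -2.63 for Kcnd3os (SE 0.46, adjusted p = 0.00423), -2.50 for Pitpnm2os1 (SE 0.64, adjusted p = 0.0201) and -2.42 for Mphosph9 (SE 0.53, adjusted p = 0.0108). It was -1.90 for Mhrt (SE 0.32), a transcript antisense to the myosin gene Myh7, -1.77 for the noncoding record of Ager (SE 0.35), the receptor gene for advanced glycation end products, and -1.50 for Mx2 (SE 0.34, adjusted p = 0.0114). Olfr29-ps1, Ppp1r2-ps7, Pcsk2os2 and Krt74 were measured in 3 groups, and their differences were -3.06, -2.69, -2.08 and -1.86. These 4 genes, Ager and Mx2 were not well above background on any deleted CoCl2 array, so the sizes of their differences rest on signal near background. After normexp and quantile normalization Ager shrank to -0.14 and Mx2 to -0.43 (limma adjusted p = 0.711 and 0.153). After quantile normalization alone they stood at -1.01 and -0.93, and both lost the call in each. No clone linked to a listed gene passed with limma over all features or adjusted over the list alone, and 1 of 20 had an unadjusted p below 0.05.

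Over all features the CoCl2 effect differed between genotypes for 14737, lower in deleted cells for 12886 and higher for 1851. With no filter it was lower for 12940 and higher for 7904, and scaled to 4 E1A control probes it was lower for 28461 and higher for 2. Among the 47149 features well above background on all 12 arrays the numbers were 4090 lower and 1794 higher, a selection that by construction leaves out more of the lower (8796) than of the higher (57). The count was 6928 after quantile normalization and 5405 after normexp and quantile normalization, which ended the call of 3 and of 7 of the 11 named genes. With slide as a block 259 features and none of the 11 named genes passed, with differences from -2.32 to -0.70. Without floxed PBS array 2, floxed CoCl2 array 2 or 3, or deleted PBS array 1 or 2, it was 8509, 7839, 8388, 7875 or 7804.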

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

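The tests of explanations in this part were chosen only after the results were seen, and 2 of them were replaced after a first result; the splits of the samples were planned.

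The CoCl2 effect differed between genotypes for 14737 features by a test of the difference itself. Among named genes the difference, deleted minus floxed, was -3.06 for Olfr29-ps1, -2.86 for Cdrt4os1, -2.69 for Ppp1r2-ps7, -2.63 for Kcnd3os, -2.50 for Pitpnm2os1, -2.42 for Mphosph9, -2.08 for Pcsk2os2, -1.90 for Mhrt, -1.86 for Krt74 and -1.77 for Ager on the log2 scale. Olfr29-ps1, Ppp1r2-ps7, Pcsk2os2, Krt74 and Ager were not well above background on any deleted CoCl2 array, so the sizes of their differences rest on signal near background and are not to be ranked with the others. Of 100 splits of the arrays drawn within genotype, 10 gave as many features, the real one included, and the highest other gave 32334. These splits can neither exclude chance for this count nor show it. All 10 kept the PBS and CoCl2 arrays of deleted cells apart, as did 15 of the 100, so they carry the CoCl2 effect of deleted cells and are not free of effects; the other 85 splits gave at most 1 feature. The split with 32334 calls exchanged the treatments of the deleted cells only, which adds the CoCl2 effects in place of subtracting them. Such large counts point to a structure of the samples, the distance of the deleted CoCl2 arrays from the rest, which all 10 carry whole.

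For the lower signal of the deleted CoCl2 arrays, which goes with most of these differences, probes near background are argued against as the whole source only: 4090 features well above background on all 12 arrays were lower and 1794 higher, and among the 17696 features with the highest signal on the other 9 arrays 1880 were lower and 1269 higher (median 0.30), against 4024 and 134 among the 17696 with the lowest (median -0.48). Less cross-hybridisation on these arrays stays open: over 8 rat and human control probes, each against the mouse probe within arrays, the difference had a median of -0.20, with 7 from -1.42 to 0.50 and a bound of -2.82 or lower for the rat Pgk1 3′ probe, which sank into background there. Control probes outside this test were read as well. From deleted PBS to deleted CoCl2 arrays, normalized log2 signal went from 1.67 to 0.63 for ERCC-00012 and from 2.18 to 0.97 for E1A a22. For E1A n9 it went from 2.88 to 3.92. In floxed cells these 3 went from 2.14 to 2.16, from 2.46 to 2.68 and from 2.51 to 2.70. Between the deleted groups raw log2 signal fell from 10.85 to 8.91 for ERCC-00012 and from 11.36 to 9.25 for a22. That of n9, a probe picked for its similar raw level, hardly moved (12.06 to 12.20), so its normalized rise comes from the scaling. The deleted PBS array on slide 3 had 74.0% of probes above background and a 75th percentile of 9.27, against 51.9% to 58.5% and 8.20 to 8.39 on the CoCl2 arrays beside it, and 96.8% of 22752 features called between slides had the same sign on 2 other arrays of slide 3 (82.8% of all features). With slide as a block 11563 features fell, yet slide stays open because all this rests on 1 deleted PBS array. That array also lay before the CoCl2 arrays on the slide, so position cannot be told apart either. An effect of genotype and CoCl2 together may also contribute: the amount of RNA was not tested, and its condition was read only from 3′ minus 5′ signal (Pgk1 2.67 ± 0.19 against 2.72 ± 0.03 in floxed CoCl2 cells, Gapdh -2.12 ± 0.14 against -1.91 ± 0.13), which leaves it open.

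For the CoCl2 response of floxed cells, of 2573 features called between slides from the other 4 arrays, 78.8% had the same sign between the CoCl2 array and a PBS array of slide 1 that were left out, against 51.5% of all features. This argues against a constant difference between slides as the source of all these changes. With 1 CoCl2 array on slide 1, an effect of slide on part of them cannot be told apart. That array also lay after the PBS arrays on its slide, so a trend with position, within and across slides, is not excluded. The response to CoCl2 named by the design stays open as well. The real split gave 3542 features and the highest of the other 9 gave 97 (0 among the 3 others that part all numbered pairs); the 10 splits are too few for a share under 0.05. The same holds for CoCl2 in deleted cells (37380, highest other 1), deletion under PBS (1060, highest other 0) and deletion under CoCl2 (47469, highest other 0), each with 1 of 10 splits as large.

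The Pgk1 control probes, outside the tested features, rose with CoCl2 in floxed cells by 1.72 (3′) and 1.82 (5′) on the log2 scale, and they also rose in deleted cells. Scaling alone is argued against for the rise in deleted cells. Pgk1 3′ minus Gapdh 3′ signal within arrays rose there by 0.72 (SE 0.13), which no scaling of an array can change. A candidate explanation is HIF-1alpha left in the deleted cells; 0 probes named Hif1a were found, so this could not be tested. Other regulators of Pgk1 stay open and untested.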

How the results depend on the processing

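The scalings to E1A control probes, the replicate block within genotype and the fit of 9 arrays were chosen only after the data were seen; all other alternatives were planned. Results that kept their side of the threshold are not repeated, not every lost call is named, and the cause of each change was not tested unless named. For deletion under PBS (1060 features), the count was 2282 after quantile normalization, 5184 after normexp and quantile normalization, 3309 scaled to probes above background on all arrays, 495 with no filter, 9302 from 6 arrays, 7613 from 9 arrays and 2816 with trend and robust. For the difference of effects (14737), it was 6928 after quantile normalization and 5405 after normexp and quantile normalization. Quantile normalization ended 1 of 28 named calls for CoCl2 in deleted cells and 3 of 32 for deletion under CoCl2. Normexp and quantile normalization ended 3 and 2 of them, among them Olfr29-ps1 in deleted cells (-0.41, limma adjusted p = 0.237). With probes above background on all 12 arrays, which leaves fewer features, 23027 changed with CoCl2 in deleted cells, 31128 with deletion under CoCl2 and 5144 in the difference. A 2-fold threshold, stricter by construction, left 2031 and 19466 for CoCl2 in floxed and deleted cells, and 611 and 25438 for deletion under PBS and CoCl2.

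With slide as a fixed block, 547 and 16377 features passed for CoCl2 in floxed and deleted cells, 1737 and 18672 for deletion under PBS and CoCl2, 259 for the difference and 356 in the overlap (2800). Under a random block for slide (correlation within slide 0.143), deletion under PBS gave 12 and the difference 7647. With the replicate number as a block the counts were 3431, 37950, 1127, 48124 and 14447, with an overlap of 2722, all within 1.5 times. The block ended the call of 1 of 9 named results of CoCl2 in floxed cells, 1 of 28 in deleted cells and 2 of 6 of deletion under PBS, and no other: the Col11a1 clone (adjusted p = 0.0704), Slc22a13b (0.0531), Serpina3h (0.0531) and Pmis2 (0.0555). The block within genotype gave 4342, 39417 and 14093 for the CoCl2 effects and their difference.

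Scaled to 4 E1A probes, the counts were 1040 for CoCl2 in floxed cells, 4088 for deletion under PBS, 28463 for the difference and 937 in the overlap. Scaled to all 10 they were 1799, 66, 10331 and 1253. The 10 include probes whose own raw signal was lower on the deleted CoCl2 arrays. The median of all features in the difference was -0.93 with 4 and 0.18 with 10 probes, against -0.02; for CoCl2 in deleted cells it was -1.20 with 4 probes and -0.31 with probes above background on all arrays, against -0.13. With 4 probes 0.765% of the calls for CoCl2 in deleted cells were upward, and 27.4% in floxed cells (27.5% with 10) against 46.3%; for deletion under PBS 2.86% were higher. By construction the 4-probe scaling lowers the deleted CoCl2 arrays, and it turned these values. For CoCl2 in deleted cells they were Brip1os -0.039, Norad -0.060, the clone at Dnajb4 -0.46, Gapdh 3′ -0.088 and Gapdh 5′ -0.22. For deletion under CoCl2 they were Snhg16 -0.0035, Rbmx -0.032, Alg13 -0.077, Bambi-ps1 -0.079, Cep41 -0.12 and Wincr1 -0.14, and the clones at Cflar -0.51, Cald1 -0.52, Dnajb4 -0.44, Atg12 -0.27, Sod1 -0.43 and Lamb1 -0.29.

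Leaving out 1 array gave 1093 to 4455 features for CoCl2 in floxed cells (lowest without floxed CoCl2 array 3), 29306 to 39465 in deleted cells, 1 to 4690 for deletion under PBS (lowest without deleted PBS array 1), 41742 to 50672 for deletion under CoCl2, 7804 to 19547 for the difference (lowest without deleted PBS array 2) and 979 to 3541 in the overlap (lowest without floxed CoCl2 array 3). Deletion under PBS also gave 2718 and 3323 without deleted CoCl2 array 1 or 2. Over these fits the named results kept the call 918 times, lost it 114 times and reversed 0 times. Shifts of gene lists and the level of Hif1a were not run, since too few members were named. Signal near background limits the falls in deleted cells with CoCl2, where 54.7% of probes were well above it.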

Other observations

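The tests of neighbouring genes, the clones and the control probes in this part were chosen only after the data were seen.

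The noncoding genes that lie beside members of 25 prepared lists, with 5 to 28 genes a list, passed camera for 0 lists in each of the 5 comparisons, with smallest adjusted p of 0.885, 0.564, 0.466, 0.616 and 0.602 and smallest unadjusted p of 0.0883, 0.0498, 0.0353, 0.067 and 0.026.

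The clones ranked were those past the threshold at protein-coding loci whose symbol is not a predicted or clone name. Among them, the largest rise in floxed cells with CoCl2 was at Prelid2 (log2 change 4.21, SE 0.55, limma adjusted p = 0.00207), and it rose by 3.06 (SE 0.55) in deleted cells. The clone at Psmd14, a proteasome subunit gene, rose by 1.62 (SE 0.39) and 1.63 (SE 0.39). Clones at Hells, a chromatin remodelling gene, and Cdk2, a cell cycle kinase gene, fell in floxed cells by 1.98 (SE 0.20) and 1.75 (SE 0.14). Both also fell in deleted cells, with log2 changes of -0.98 (SE 0.20, limma adjusted p = 0.00203) and -1.28 (SE 0.14, adjusted p = 9.12e-05). Of 545 clones at protein-coding loci, the CoCl2 effect was lower in deleted than in floxed cells for 65 and higher for 8. The Hells clone was among the 8, as its fall was smaller in deleted cells (1.00, SE 0.28, adjusted p = 0.0289). That call ended with slide as a block (0.51, adjusted p = 0.537) and under the scalings to 4 (0.08, adjusted p = 0.883) and 10 E1A control probes (adjusted p = 0.0623). The Psmd14 rise in deleted cells ended with slide as a block (1.25, adjusted p = 0.109) and under the 4-probe scaling (0.56, adjusted p = 0.188). In floxed cells it ended with slide as a block (1.10, adjusted p = 0.421), with the replicate number as a block (adjusted p = 0.0538) and under both scalings (adjusted p = 0.0646 and 0.0708). The Prelid2 rises in floxed and deleted cells with slide as a block were 3.85 and 2.26 (adjusted p = 0.0608 and 0.0572), while the floxed falls at Hells and Cdk2 held. After normexp and quantile normalization the Prelid2 rises were 1.94 and 1.86, and under the 4-probe scaling 4.05 and 1.99.

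As a measure of RNA quality, the 3′ minus 5′ signal of Pgk1 was 2.82 ± 0.02, 2.72 ± 0.03, 3.07 ± 0.05 and 2.67 ± 0.19 (SD, n = 3) in floxed PBS, floxed CoCl2, deleted PBS and deleted CoCl2 cells. For Gapdh it was -2.32 ± 0.02, -1.91 ± 0.13, -2.25 ± 0.09 and -2.12 ± 0.14.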
